A study of Homo sapiens with 20 samples.

How the data were processed

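Single cells from the peripheral blood and the hematoma of 10 patients with intracerebral hemorrhage were measured by 10x Genomics 3' RNA sequencing, 1 library per patient and tissue and 20 libraries in all. Per the labels, hematoma fluid was strained at 40 µm, and blood and hematoma cells were depleted of granulocytes, treated to lyse red cells and spun in Percoll before loading. The design text of the series names cerebrospinal fluid in place of hematoma, and the sample labels, which name hematoma, were followed; which fluid was sampled could not be settled from the files. The deposited matrices hold raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger, 3.1.0 per the labels and 9.0.1 per the file headers. The genome is GRCh38 per the labels and the annotation release is not stated, so gene positions were taken by gene identifier from GENCODE release 29. Values that are not counts in the deposited files are of another kind (other), namely barcodes and gene names. The files list 33538 genes, of which 110, being XIST, TSIX and genes of chromosome Y, were left out and 33428 used.

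In 4 patients the library name in the blood label stood in the file names of the hematoma sample and the reverse. Neither was taken as right, and these 8 libraries were kept out of the main comparisons and entered as alternatives, as labelled and exchanged. The other 6 patients gave 12 libraries. The 20 libraries held 9596909 to 120865501 UMIs in 648 to 12524 barcodes each. Of 124745 barcodes, 9473 failed the filter of at least 200 genes and at most 20% mitochondrial UMIs. A further 6822 were called doublets by Scrublet scores at an expected rate of 0.8% per 1000 cells, since automatic calling gave under 0.5% in 8 libraries. This left 108450 cells. Intervals and limits cover counting error only.

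Cells of all 20 libraries were clustered together without use of the group in scanpy 1.11.5 (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1 with leidenalg 0.10.2, seed 1). Clusters were named from marker lists of 17 classes fixed before the data were examined. A name needed at least 3 markers over 2-fold above the other cells and detected in over 10% of the cluster, and a share of its markers 10 percentage points over that of the next class. Clusters of under 20 cells, mostly of doublets or led by genes of another class also stayed unnamed. Counts were summed per library and class where at least 20 cells were present. Genes were tested with edgeR 4.0.16 (TMM, quasi-likelihood, its low-count filter) in R 4.3.3, and DESeq2 1.42.0 was an alternative. Shares and quality measures were compared by exact two-sided permutation of the libraries. The 30 gene lists were fixed before the data were examined, 24 of them tested in monocyte-like and 22 in each lymphocyte class. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, which called 15, 5, 4 and 5 lists in monocyte-like, T, NK and B cell-like cells. In 9 of 90 list tests the median, mean and test differed in sign, none of them called. Adjusted p-values used the Benjamini-Hochberg method over the genes, lists, classes or measures of each comparison, at a threshold of 0.05. Numbers were computed with python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots with matplotlib 3.10.9.

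The rule for named genes was fixed before the data were examined. It took, among genes past the threshold with the same sign in every patient pair and a mean of at least 50 CPM in the higher group, the 8 largest rises and 8 largest falls, and up to 3 members of each list with the lowest adjusted p under 0.05. A list with no such member gave its member with the highest mean CPM. XIST, Y-linked genes, receptor segments and clone-named genes were never named, nor marker genes in the microglia comparison. The rule gave 272 genes over the 6 comparisons, 253 of them called, and the call of 72 ended when 1 patient was left out. For length, the text names 117 of them. These were chosen after the values were seen, as those whose call held under each alternative in which they were tested except all 10 patients as labelled, so their stability is a result of the choice. Genes that led the clusters of microglia-like cells were left out for the same reason, as they define the classes compared.

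The replicate number in the labels pairs the blood and hematoma of a patient. After the group means were removed, the 2 libraries of a patient correlated over genes at 0.0601 to 0.387 in monocyte-like, 0.317 to 0.532 in T, 0.206 to 0.393 in NK and 0.261 to 0.335 in B cell-like cells, against medians of -0.0324, -0.0812, -0.0509 and -0.0617 between patients. The patient as a block was an alternative fixed before the data were examined. No 2 of the 20 libraries were identical (190 pairs, highest correlation of log2 CPM 0.992). Other alternatives were DESeq2, no low-count filter, doublets kept, a stricter cell filter (500 genes, 10% mitochondrial UMIs), cells thinned to 1000 UMIs, Leiden resolution 0.5, monocyte-like cells without nonclassical clusters, at least 10 cells per sum, and leaving out each patient. The alternatives of at least 100 cells per sum and of leaving out cells whose barcode stood in another library at 5 or more times the UMIs were added after the data were seen.

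The tests were tested on simulated data, with 100 genes changed by a log2 of 1 and 100 by 2 in libraries of the same size. Each gene had 1 dispersion for both groups and no patient effect was simulated, so the rates may not carry over to the data. In monocyte-like sums edgeR recovered 19% and 75% of them, with 5.1% of its calls false, and DESeq2 36% and 81%, with 20.4% false. In T, NK and B cell-like sums edgeR recovered 40%, 41% and 21% of the smaller and 85%, 90% and 85% of the larger changes, with 6.7%, 7.7% and 5.4% false. In the microglia comparison it recovered 6% and 65%, with 14.5% false, and in the interaction 9% and 50%, with 3.3% false. None of 23 random lists was called. The simulated genes were drawn independently of each other, so this cannot tell how the list test behaves with correlated genes.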

Results

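Intracerebral hemorrhage is bleeding into the brain that leaves a pool of clotted blood, the hematoma. Droplet single-cell RNA libraries were made from peripheral blood and from the hematoma of 10 patients, 1 library of each per patient and 20 in all. The title of the study names microglia, the resident macrophages of the brain, and monocytes, the circulating cells that enter tissue and become macrophages there. The design thus sets leukocytes of the hematoma against leukocytes in the blood of the same patients. In 4 patients the library names in the labels and in the file names were crossed between blood and hematoma, and these 8 libraries entered no main comparison. The comparisons used the blood and hematoma libraries of the other 6 patients. Their blood libraries held 61955405 to 79723056 unique molecular identifiers (UMIs) and their hematoma libraries 9596909 to 65281637. After filtering, 42502 blood cells and 15695 hematoma cells were analysed. Counts were summed per library and cell class, and levels are given as CPM, the counts of a gene scaled to the total of its library and class, mean ± SD over libraries. Gene positions are on GRCh38, from GENCODE release 29, and p-values were adjusted by the Benjamini-Hochberg method.

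Neural or glial-like and microglia-like cells stood mainly in hematoma, and platelet-like cells mainly in blood. Neural or glial-like cells made up 16.6% ± 11.7 (SD, n = 6) of hematoma cells and 0.580% ± 0.747 (n = 6) of blood cells, higher in 6 of 6 patients (exact two-sided permutation test, p = 0.00866, adjusted p = 0.0649). Microglia-like cells made up 1.38% ± 0.991 of hematoma cells and were found in 5 of 6 patients (exact permutation p = 0.0152, adjusted p = 0.0758). None was named among 42502 blood cells, which allows a share of up to 0.00706% for cells so named. Cluster 32 is in neither figure. It had 43.75% of the microglia and 40.0% of the monocyte markers, stayed unnamed, and held 26 blood and 154 hematoma cells. Monocyte-like cells made up 53.1% ± 15.6 of blood and 20.3% ± 24.0 of hematoma, lower in 6 of 6 patients (exact permutation p = 0.0260, adjusted p = 0.0758). T cell-like cells made up 20.9% ± 10.9 of blood and 40.9% ± 26.6 of hematoma, higher in 4 of 6 patients (exact permutation p = 0.115, adjusted p = 0.246). NK cell-like cells made up 7.10% ± 4.18 and 9.41% ± 7.00, and B cell-like cells 7.96% ± 1.77 and 4.95% ± 4.84, with adjusted p of 0.577 and 0.273 in the same exact test.

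Of 15 classes tested, platelet-like cells alone passed the adjusted threshold of 0.05. They fell from 2.12% ± 2.36 of blood cells to 0.00922% ± 0.0145 of hematoma cells, lower in 6 of 6 patients (exact permutation p = 0.00217, adjusted p = 0.0325). The fall kept its direction with any 1 patient left out and turned with all 10 patients as labelled. The call ended with the stricter cell filter, with pairs (exact sign-flip permutation, p = 0.0312, the smallest that 6 pairs allow, adjusted p = 0.117) and without any 1 patient other than replicate 6, where the design leaves few splits. Before loading, hematoma fluid was strained at 40 µm, granulocytes were depleted, red cells lysed and cells spun in Percoll, each of which can set these shares. Blood was expected to hold no brain cells, and the 273 neural or glial-like cells there had a median of 619 UMIs, against 15414 in hematoma.

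**Figure D1:**
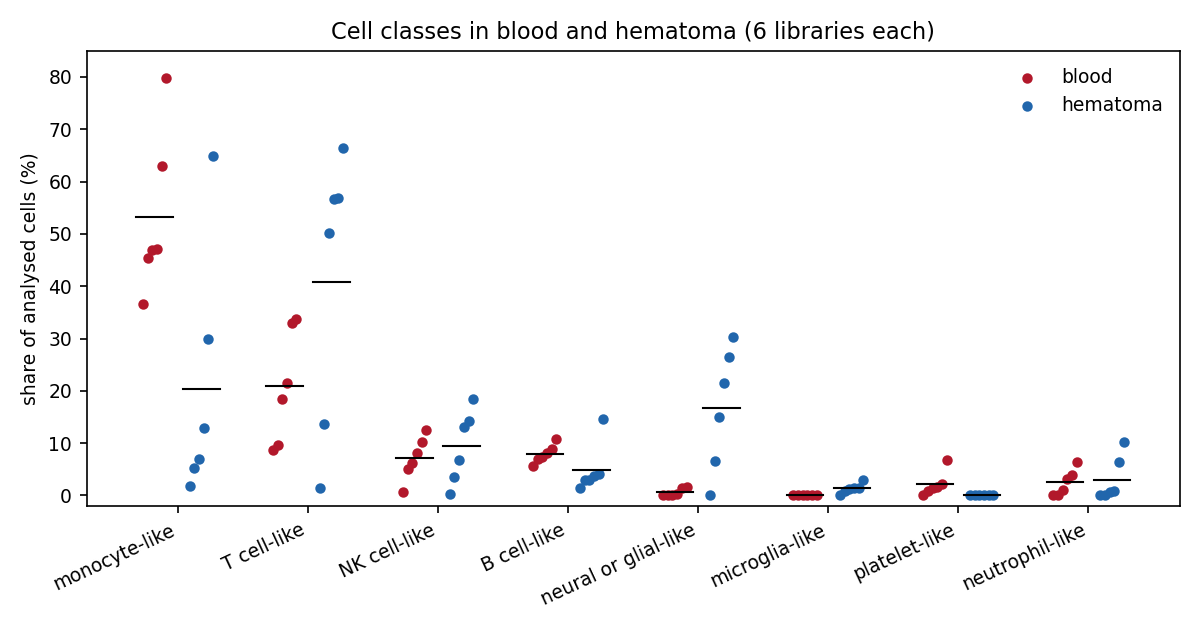
Share of analysed cells (%, y axis) in 8 cell classes (x axis), in 6 blood libraries (red) and 6 hematoma libraries (blue), with points for libraries and black lines for means. Monocyte-like cells averaged 53.1% in blood and 20.3% in hematoma, and neural or glial-like cells 0.580% and 16.6%.

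Monocyte-like cells of hematoma carried macrophage RNA at levels far above those of blood monocytes. SPP1 (chromosome 4, 87975650 to 87983426), which encodes the secreted matrix protein osteopontin, rose from 0.254 ± 0.249 CPM in blood to 8336 ± 7920 CPM in hematoma (n = 6 each), a log2 fold change of 15.04 ± 1.40 (SE, edgeR adjusted p = 7.81e-06), higher in 6 of 6 patients. APOE (chromosome 19, 44905754 to 44909393), a carrier of lipids and cholesterol, rose from 0.220 ± 0.232 to 2682 ± 3118 CPM, by 13.60 ± 1.90 on the log2 scale (edgeR adjusted p = 0.000161). Levels of APOE ranged from 2.19 to 6587 CPM over the hematoma libraries. Its neighbour APOC1 rose by 12.83 ± 1.62. Of 26 tested genes for lipid handling and phagocytosis in macrophages, 21 rose and 0 fell, or 24 and 0 when adjusted over the list alone. Among them were the lysosomal protease CTSL, at 19.4 ± 4.65 and 1503 ± 779 CPM (log2 fold change 6.27 ± 0.42), the fatty acid carrier FABP5 (5.28 ± 0.39) and the lipid droplet protein PLIN2 (5.24 ± 0.43). The list was higher by camera (adjusted p = 5.32e-16), a call lost with an estimated correlation between genes (adjusted p = 0.106 with an estimated correlation).

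Most cytokine and hypoxia genes tested rose in the same cells. Of 25 inflammatory cytokine and chemokine genes, 18 rose and 1 fell (20 and 1 adjusted over the list alone). CXCL5, a neutrophil attractant, reached 3103 ± 4288 CPM from 0.241 ± 0.158 CPM (log2 fold change 13.64 ± 1.57, edgeR adjusted p = 3.71e-05, n = 6). CCL7 and CCL20, which attract monocytes and lymphocytes, rose by 13.25 ± 1.13 and 13.14 ± 1.52, and IL10, an anti-inflammatory cytokine, by 3.05 ± 0.31. All 3 were higher in 6 of 6 patients. Of 24 hypoxia response genes 22 rose and 0 fell (23 and 0 adjusted over the list alone), among them the glucose transporter SLC2A1 (5.35 ± 0.57) and the mitophagy receptor BNIP3 (5.51 ± 0.63). Of 20 glycolysis genes 14 rose and 1 fell (16 and 1 adjusted over the list alone), among them ENO2 (8.26 ± 0.97) and LDHA (2.58 ± 0.38), whose pseudogenes make its level uncertain. The 3 lists had camera adjusted p of 2.70e-09, 5.37e-12 and 2.91e-07, and 0.177, 0.207 and 0.207 with an estimated correlation.

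Some repair, prostaglandin and stress genes also rose, and other members of these lists did not pass the test. Of 22 genes for matrix remodelling and wound repair 14 rose and 1 fell (16 and 1 adjusted over the list alone). The plasminogen activator PLAU rose by 7.11 ± 0.64, the protease MMP19 by 6.37 ± 0.71 and the sheddase ADAM9 by 1.58 ± 0.14 (SE of log2 fold changes, n = 6 against 6). Of 19 genes for the synthesis of prostaglandin E2 and the response to it, 10 rose and 1 fell, the same counts as adjusted over the list alone. PTGES, the synthase, rose from 0.715 ± 0.520 to 148 ± 140 CPM (7.69 ± 1.13) and was higher in 5 of 6 patients, while EREG (3.65 ± 0.56) and VEGFA (4.09 ± 0.64) were higher in 6 of 6. Of 23 immediate early and heat shock genes 12 rose and 0 fell (13 and 1 adjusted over the list alone), including the small heat shock protein gene HSPB1 (3.89 ± 0.40). Of 18 endoplasmic reticulum stress genes 10 rose and 1 fell, in both adjustments, including the chaperone gene HSPA5 (1.80 ± 0.35). Camera adjusted p for these 4 lists were 4.76e-09, 0.00198, 0.000823 and 0.000558, and 0.106, 0.226, 0.335 and 0.207 with an estimated correlation.

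Some genes that circulating monocytes express fell. Of 19 alarmin and secretory granule genes 11 fell and 1 rose (12 and 1 adjusted over the list alone). MNDA, a nuclear antigen of myeloid cells, fell from 1325 ± 233 to 233 ± 153 CPM (log2 fold change -2.50 ± 0.33), and the lectin gene FCN1 from 1630 ± 189 to 317 ± 219 CPM (-2.36 ± 0.37), both lower in 6 of 6 patients. Of 25 ribosomal protein genes 6 fell and 0 rose (9 and 0 adjusted over the list alone), and these have many pseudogenes. Some members of the platelet and neutrophil lists fell as well. Of 11 platelet genes 4 fell and 1 rose, in both adjustments, with CAVIN2 at -3.65 ± 0.57 and NRGN at -2.21 ± 0.35. Of 14 neutrophil genes 6 fell and 1 rose (9 and 3 adjusted over the list alone), with VNN2 at -2.48 ± 0.33. The 4 lists were lower by camera (adjusted p = 7.23e-06, 4.08e-05, 0.00261 and 0.0321), with 0.168, 0.438, 0.207 and 0.281 from an estimated correlation. Outside the lists, the cytokine receptor FLT3 (-3.27 ± 0.56), the adhesion molecule JAML (-2.99 ± 0.35), the cyclin CCND3 (-2.79 ± 0.36) and the histone gene HIST1H2AC (-3.11 ± 0.55) fell, and the fatty acid carrier FABP4 (12.03 ± 1.20) and the phosphatase DUSP4 (10.68 ± 1.09) rose.

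Other lists held members that moved without a call for the list. Heme and iron handling had 7 of 19 genes up and 3 down (9 and 3 adjusted over the list alone, camera adjusted p = 0.107). HMOX1, which breaks down heme, rose from 128 ± 46.8 to 1641 ± 1217 CPM (log2 fold change 3.69 ± 0.47, edgeR adjusted p = 7.63e-05, n = 6), the scavenger receptor MARCO by 3.21 ± 0.56, and the ferritin gene FTH1, whose pseudogenes make it uncertain, by 2.17 ± 0.34. Among 19 NRF2 targets of the oxidative stress response, 5 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.107), the cystine transporter SLC7A11 by 4.91 ± 0.56 and TKT by -1.47 ± 0.27. In the complement list 4 of 16 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.562), CD59 by 3.29 ± 0.37 and CFP by -1.78 ± 0.38. Of 20 glucocorticoid response genes 3 rose and 6 fell (5 and 8 adjusted over the list alone, camera adjusted p = 0.107), FKBP5 by -2.05 ± 0.40. Of 16 trafficking genes 5 rose and 7 fell (5 and 8 adjusted over the list alone, camera adjusted p = 0.0879), ITGB1 by 1.93 ± 0.30 and SELPLG by -1.58 ± 0.23. NF-kB targets had 3 of 16 up and 1 down (4 and 1 adjusted over the list alone, camera adjusted p = 0.562), IER3 by 2.17 ± 0.49 and TNFAIP2 by -1.53 ± 0.31. Of 9 genes of brain tissue 4 rose and 1 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.0750), with CRYAB at 8.01 ± 0.94 from 0.0300 ± 0.0336 to 9.50 ± 8.86 CPM. Of 23 type I interferon genes 1 fell, of 14 MHC class II genes 2 fell, of 12 cell cycle genes 4 rose and 1 fell, of 32 oxidative phosphorylation genes 4 fell, and none of 4 erythroid genes changed. Adjusted over the list alone these counts were the same, but for oxidative phosphorylation, where 0 passed. Their camera adjusted p were 0.152, 0.0879, 0.303, 0.423 and 0.439. With the patients as blocks, the interferon and MHC class II lists were lower by camera (adjusted p = 1.25e-05 and 0.00624). Without blocks they had adjusted p = 0.766 and 0.605 with an estimated correlation, which was not run with blocks.

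In all, 3245 of 14478 genes tested differed in monocyte-like cells, 1765 higher and 1480 lower in hematoma (edgeR quasi-likelihood test, adjusted threshold 0.05, 6 libraries against 6). The hematoma libraries held 48 to 818 monocyte-like cells each and the blood libraries 2615 to 6090. DESeq2 called 4800, 64.6% of them higher against 54.4% in edgeR. No gene was called with all 10 patients as labelled, where 780 had an unadjusted p under 0.05, and 1483 were called with cells thinned to 1000 UMIs. Blood monocyte-like cells lay mainly in clusters 0, 2, 11, 1 and 10, and those of hematoma in cluster 19, led by FN1 and CXCL5, in cluster 34, led by GPNMB and CCL2, and in clusters 39, 41 and 2. Library medians were 9600 to 12270 UMIs per monocyte-like cell in blood and 10620 to 17330 in 5 hematoma libraries, while hematoma replicate 9 stood apart at 678 UMIs and 532 genes. Without replicate 9 the count of called genes was 2465.

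**Figure D2:**
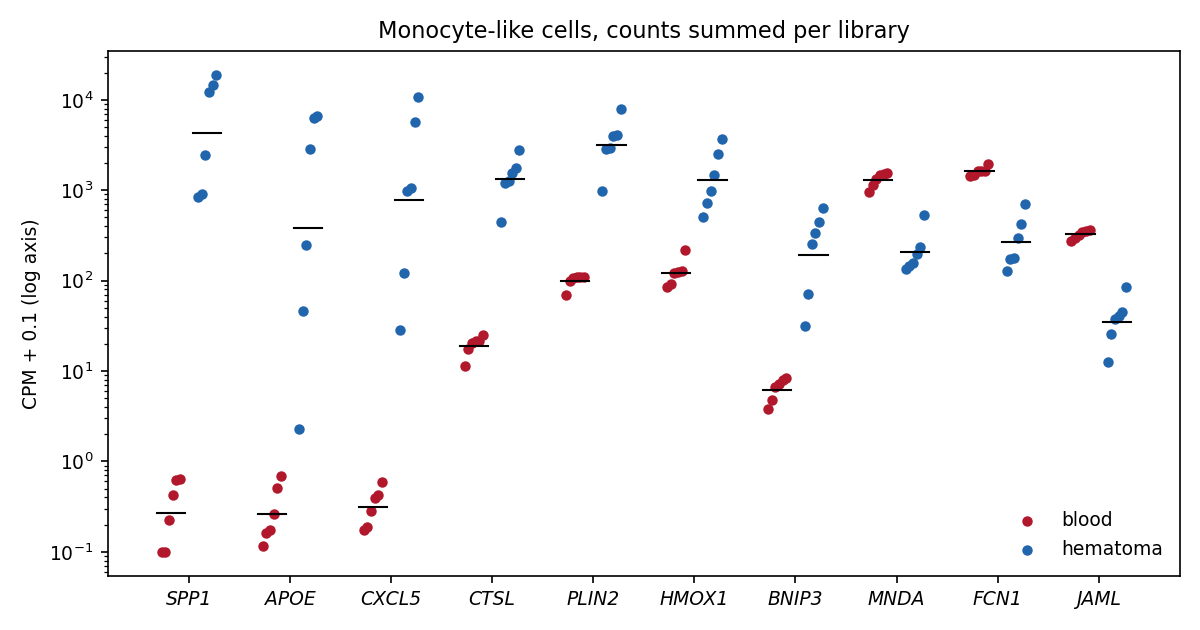
CPM plus 0.1 (log axis) of 10 genes in monocyte-like cells, summed per library, in 6 blood libraries (red) and 6 hematoma libraries (blue), with points for libraries and black lines for geometric means. SPP1 ranged from 0 to 0.546 CPM in blood and from 836 to 19000 CPM in hematoma, and MNDA from 953 to 1567 and from 133 to 536 CPM.

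T cell-like cells of hematoma had higher RNA of some hypoxia response genes and of some heat shock genes. Of 23 immediate early and heat shock genes 4 rose and 1 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.00843), a call lost with an estimated correlation (adjusted p = 0.675 with an estimated correlation). HSPA6 (chromosome 1, 161524540 to 161526910), an inducible heat shock gene, rose from 1.45 ± 1.21 CPM (n = 6) to 67.1 ± 58.9 CPM (n = 5), a log2 fold change of 5.52 ± 0.58 (SE, edgeR adjusted p = 0.000419), higher in 5 of 5 patients. HSPA1A, uncertain because its copy HSPA1B is nearly identical, rose by 3.20 ± 0.51. The TGF-beta target genes PMEPA1 (3.22 ± 0.42) and SKIL (2.89 ± 0.32) rose in 5 of 5 patients. Of 22 hypoxia response genes 11 rose and 0 fell (18 and 1 adjusted over the list alone), among them the collagen prolyl hydroxylase P4HA1, at 33.9 ± 3.24 and 145 ± 76.1 CPM (2.10 ± 0.32), and PFKFB3 (1.37 ± 0.26). Of 19 glycolysis genes 8 rose and 0 fell (13 and 1 adjusted over the list alone), including PGK1 (1.08 ± 0.16), which has pseudogenes. Camera adjusted p were 7.63e-09 and 3.07e-07, and 0.234 for both with an estimated correlation. SPP1 stood in hematoma T cell-like cells at 0.791% of its level over all hematoma cells.

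Some genes of adhesion, of platelets and of monocytes fell in the same cells. The alarmin genes S100A8 (64.4 ± 23.7 to 3.40 ± 3.33 CPM, log2 fold change -4.81 ± 0.55) and S100A9 (-4.66 ± 0.49), the monocyte gene LYZ (-4.65 ± 0.64) and the platelet gene PF4 (-6.86 ± 0.83) fell in 5 of 5 patients. UMIs of S100A8, S100A9 or LYZ were found in 68.4% of blood and 4.29% of hematoma lymphocyte-like cells. BCL2, an inhibitor of cell death, fell from 673 ± 231 to 196 ± 62.1 CPM (-1.79 ± 0.28). Of 23 trafficking genes 7 fell and 0 rose (11 and 2 adjusted over the list alone, adjusted p = 0.426 with an estimated correlation), among them the integrin genes ITGA4 (-1.27 ± 0.22) and ITGAL (-1.24 ± 0.22). CD40LG, the helper signal to B cells, fell by 1.33 ± 0.17 on the log2 scale, as the 1 gene of 19 for T and NK cell activation that fell, against 1 that rose (2 and 2 adjusted over the list alone, camera adjusted p = 0.279). Of 18 naive and central memory genes 3 fell and 0 rose (5 and 0 adjusted over the list alone), with CD27 at -1.31 ± 0.22. Of 20 cell cycle genes 4 fell (12 adjusted over the list alone), of 20 cytotoxic genes 2 (2), of 13 cytokine genes 1 (2) and of 10 platelet genes 7 (8, adjusted p = 0.398 with an estimated correlation), and none rose. RGS2, a glucocorticoid response gene, rose by 2.17 ± 0.29.

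Camera called 11 of 22 lists in T cell-like cells. Besides hypoxia and glycolysis, immediate early and heat shock genes were higher (adjusted p = 0.00843). Lower lists were cell cycle (3.07e-07), cytotoxic (6.00e-07), platelet (3.88e-06), oxidative phosphorylation (3.07e-05, 0 of 32 genes called), trafficking (0.000349), naive and central memory (0.0228), cytokines (0.0245) and ribosomal proteins (0.0246, 0 of 25 genes called). With an estimated correlation the adjusted p of these 9 lists were 0.675, 0.398, 0.534, 0.398, 0.675, 0.426, 0.689, 0.534 and 0.740, in the same order. NF-kB targets (0 of 15 genes called) had an adjusted p of 0.222, and of 0.0455 with the patients as blocks. Without blocks they had adjusted p = 0.740 with an estimated correlation. The other 10 lists had adjusted p from 0.0689 to 0.949.

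In T cell-like cells 648 of 14056 genes differed, 361 higher and 287 lower (edgeR, 6 libraries against 5). With the patients as blocks, which leaves the 5 complete pairs, 1889 were called, against 438 in the same libraries without blocks. The count was 154, 318, 391 and 293 without replicate 6, 7, 8 and 9, and 289 with cells thinned to 1000 UMIs. As labelled, with all 10 patients, no gene was called and 314 had an unadjusted p under 0.05 (edgeR). Blood T cell-like cells lay mainly in clusters 9, 13, 15, 20 and 23, and those of hematoma in clusters 6, 8, 27 and 23. Clusters 9 and 15, which CD40LG helped lead, held 34.7% and 12.7% of T cell-like cells in blood. In hematoma they held 1.54% and 2.89%. In each class, sums cannot tell a change within cells from a change in the mix of clusters.

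NK cell-like cells of hematoma had less RNA of some cytotoxic genes and more of some hypoxia response genes. Of 20 cytotoxic effector genes 7 fell and 0 rose (11 and 0 adjusted over the list alone). They included the protease gene GZMA, from 1719 ± 124 CPM (n = 6) to 807 ± 256 CPM (n = 5), a log2 fold change of -1.10 ± 0.21 (SE, edgeR adjusted p = 0.00378). TBX21, the transcription factor T-bet, fell by 1.03 ± 0.18 on the log2 scale, and the chemokine receptor CX3CR1, of the same list, by 2.78 ± 0.32. The receptor CD160 fell from 118 ± 24.0 to 25.4 ± 4.76 CPM (-2.19 ± 0.20). PMEPA1 (chromosome 20, 57648392 to 57711536) rose from 0.326 ± 0.612 to 63.8 ± 39.3 CPM (7.36 ± 0.58, edgeR adjusted p = 3.86e-06), and the adaptor GAB2 by 2.74 ± 0.31. The integrin ITGAE (1.09 ± 0.18) and RGS1 (2.41 ± 0.38), both linked to tissue residency, rose in 5 of 5 patients, while the residency list had 3 of 11 up and 4 down (4 and 4 adjusted over the list alone, camera adjusted p = 0.664). Of 20 hypoxia response genes 11 rose and 0 fell (16 and 0 adjusted over the list alone), with BNIP3L at 2.11 ± 0.27 and P4HA1 at 2.08 ± 0.32. Of 17 glycolysis genes 10 rose and 0 fell (12 and 0 adjusted over the list alone), with LDHA at 1.70 ± 0.18 and PGK1 at 1.26 ± 0.18, both with pseudogenes.

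Some mitochondrial, adhesion and heat shock genes also changed in NK cell-like cells, and the calls of these lists were lost with an estimated correlation (adjusted p = 0.707, 0.173 and 0.758 with an estimated correlation). Of 32 oxidative phosphorylation genes 6 fell and 0 rose (7 and 0 adjusted over the list alone), NDUFB7 by 1.13 ± 0.18 and NDUFB2 by 1.04 ± 0.19. Of 17 trafficking genes 9 fell and 2 rose, in both adjustments, with ITGAL at -0.97 ± 0.15. Of 23 immediate early and heat shock genes 7 rose and 0 fell (8 and 1 adjusted over the list alone), with HSPA1A (3.83 ± 0.56) and HSPA1B (4.71 ± 0.67), which share reads. TXNIP, a glucose-sensitive gene, fell from 2235 ± 402 to 771 ± 124 CPM (-1.53 ± 0.19). S100A8 (-4.73 ± 0.46) and LYZ (-4.51 ± 0.61) fell, and of 6 platelet genes 4 fell in both adjustments. PPBP had 607 counts in blood and 5 in hematoma, and PF4 368 and 1, a ratio of 214 with a counting interval of 38.1 to 8469. SPP1 stood at 0.990% of its level over all hematoma cells.

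Camera called 8 of 22 lists in NK cell-like cells, those of hypoxia (adjusted p = 1.18e-08), glycolysis (1.20e-07) and heat shock (0.0171) as higher and those of cytotoxic (1.13e-08), oxidative phosphorylation (4.33e-06), ribosomal (0.000489, 0 of 25 genes called), trafficking (0.000943) and platelet genes (0.00158) as lower. With an estimated correlation the adjusted p were 0.160, 0.160, 0.758, 0.131, 0.707, 0.758, 0.173 and 0.545. NF-kB targets (2 of 15 up in both adjustments, adjusted p = 0.0627) and erythroid genes (0 of 5, adjusted p = 0.257) were called with the patients as blocks (adjusted p = 0.00844 and 0.0204). Without blocks both had adjusted p = 0.758 with an estimated correlation. The other 12 lists had adjusted p from 0.222 to 0.682. In all, 1080 of 11560 genes differed, 562 higher and 518 lower (edgeR, 6 libraries against 5). With the patients as blocks 2066 were called in the 5 complete pairs, against 994 in the same libraries without blocks. The count was 509, 659, 645 and 454 without replicate 6, 7, 8 and 9, 508 with thinned cells and 0 as labelled, where 233 had an unadjusted p under 0.05 (edgeR). Blood NK cell-like cells lay in clusters 3 and 16, and 93.5% of those of hematoma in cluster 12. The sums cannot tell a change within cells from this change of clusters.

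B cell-like cells of hematoma had more RNA of some NF-kB targets. Of 13 such genes 8 rose and 0 fell (10 and 0 adjusted over the list alone). The feedback inhibitor TNFAIP3 (chromosome 6, 137867188 to 137883312) rose from 21.8 ± 7.25 CPM (n = 6) to 124 ± 110 CPM (n = 4), a log2 fold change of 2.56 ± 0.42 (SE, edgeR adjusted p = 0.00408), and the adaptor TRAF1 by 3.47 ± 0.62. The homing receptor CCR7 rose by 1.47 ± 0.27. PAM (18.9 ± 4.96 to 217 ± 76.9 CPM, 3.53 ± 0.25), PKP4 (3.47 ± 0.25), STAT4 (3.57 ± 0.32) and the phosphodiesterase gene PDE3B (3.69 ± 0.38) rose in 4 of 4 patients. HSPA1A (3.71 ± 0.55) and ATF3 (3.06 ± 0.49) were among 6 of 23 immediate early and heat shock genes that rose, with 0 that fell (9 and 0 adjusted over the list alone). Of 20 hypoxia response genes 10 rose and 0 fell (15 and 0 adjusted over the list alone), with P4HA1 at 2.01 ± 0.24. Of 19 glycolysis genes 6 rose and 0 fell (12 and 0 adjusted over the list alone), with LDHA, which has pseudogenes, at 1.83 ± 0.25. The phosphatase PTPN6, which restrains receptor signals, fell from 245 ± 77.7 to 50.9 ± 22.7 CPM (-2.30 ± 0.33). S100A8 (-5.24 ± 0.60) and LYZ (-5.14 ± 0.65) fell, and SPP1 stood at 0.861% of its level over all hematoma cells.

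Camera called 11 of 22 lists in B cell-like cells. Higher were hypoxia and NF-kB (adjusted p = 5.16e-09 for both), glycolysis (1.96e-07), heat shock (0.000135), activation (0.0210, 2 of 14 up, 6 adjusted over the list alone) and tissue residency (0.0329, 2 of 7 up, 3 up and 1 down adjusted over the list alone). Lower were ribosomal (6.87e-08) and oxidative phosphorylation genes (4.23e-05), with 0 genes called in either, platelet genes (0.00225, 5 of 9 down, 7 adjusted over the list alone), trafficking (0.00501, 6 of 16 down and 2 up, 9 and 2 adjusted over the list alone) and cytotoxic genes (0.00507, 2 of 6 down in both adjustments). With an estimated correlation the adjusted p were 0.209 for hypoxia, NF-kB, glycolysis, residency and trafficking, 0.298 for cytotoxic genes, 0.484 for heat shock, 0.525 for activation, ribosomal and platelet genes and 0.595 for oxidative phosphorylation. Type I interferon genes (3 of 19 down in both adjustments, adjusted p = 0.198) and erythroid genes (0 of 4, adjusted p = 0.719) were lower with the patients as blocks (adjusted p = 0.00635 and 0.0372). Without blocks they had adjusted p = 0.755 and 0.813 with an estimated correlation. The other 9 lists had adjusted p from 0.0685 to 0.902. In all, 613 of 11533 genes differed, 378 higher and 235 lower (edgeR, 6 libraries against 4). The count was 168 without replicate 6, 347 without replicate 7, 210 with thinned cells and 0 as labelled, where 287 had an unadjusted p under 0.05 (edgeR). Blood B cell-like cells lay in clusters 7 and 18 and those of hematoma in clusters 33, 18 and 7.

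**Figure D3:**
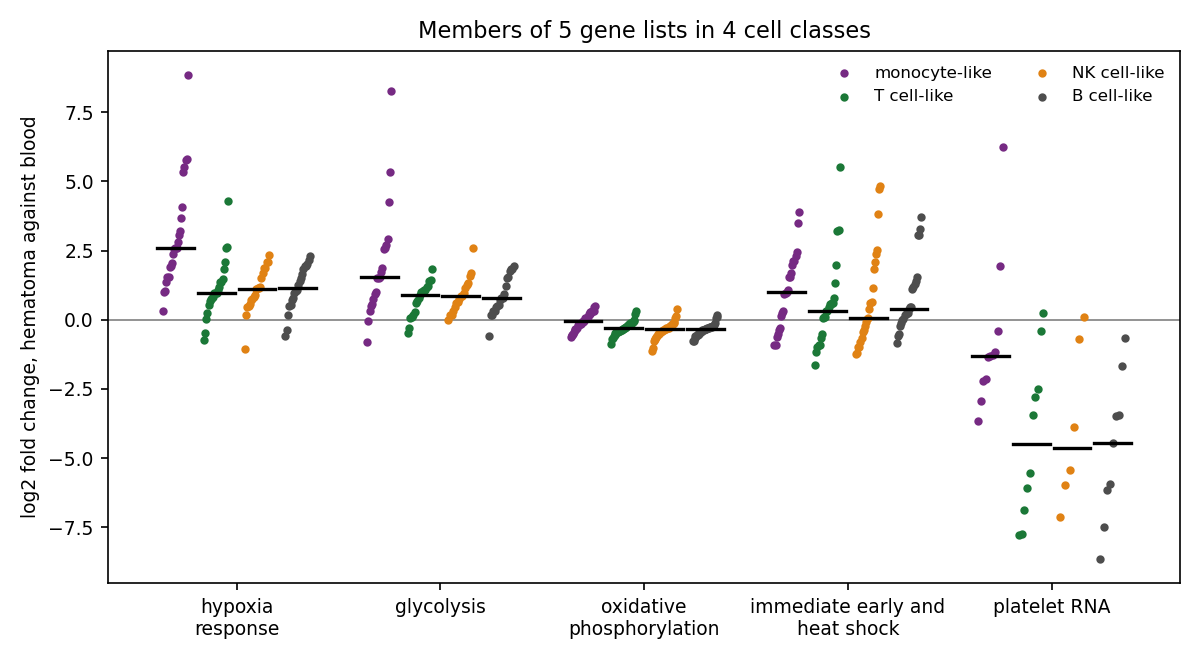
Log2 fold change, hematoma against blood (y axis), of the tested members of 5 gene lists (x axis) in monocyte-like (purple), T cell-like (green), NK cell-like (orange) and B cell-like cells (gray), with points for genes and black lines for medians. Median log2 fold changes of hypoxia response genes were 2.60, 0.96, 1.12 and 1.16 in that order, and those of platelet genes -1.32, -4.50, -4.65 and -4.45.

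The change from blood to hematoma differed between monocyte-like and T cell-like cells, tested as the interaction of class and tissue. CXCL5 had the largest difference named, 11.46 ± 1.37 on the log2 scale (SE, edgeR adjusted p = 4.70e-05), from 0.251 to 3674 CPM in monocyte-like cells and from 0.237 to 3.36 CPM in T cell-like cells. PPBP, a platelet chemokine gene, rose in monocyte-like cells (6.25, edgeR adjusted p = 0.00425) and fell in T cell-like cells (-5.54, edgeR adjusted p = 0.0112), a difference of 10.41 ± 0.84. The amino acid transporter SLC16A10 (10.14 ± 0.63), the lipase inhibitor ANGPTL4 (9.44 ± 0.60), CCL20 (9.90 ± 1.17) and TFPI, an inhibitor of coagulation (9.20 ± 0.85), rose more in monocyte-like cells. RGS2 fell in monocyte-like cells (-1.57, edgeR adjusted p = 0.00257) and rose in T cell-like cells (2.17, edgeR adjusted p = 0.00139), a difference of -3.71 ± 0.47. HSPA6 rose more in T cell-like cells (difference -3.52 ± 0.55). DACH1, the lectin receptor CLEC4A and JAML fell in monocyte-like cells by log2 fold changes of -3.12, -2.36 and -2.99. Their differences from the T cell-like effect were -3.97 ± 0.61, -3.77 ± 0.37 and -3.29 ± 0.30, with T cell-like CPM of 0.788 and 0.874, 2.16 and 5.71, and 38.1 and 32.6 in blood and hematoma. In all, 2339 of 16210 genes differed between the effects, 1288 with a higher and 1051 with a lower change in monocyte-like cells, and 0 as labelled, where 780 had an unadjusted p under 0.05 (edgeR).

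Microglia-like cells were compared with monocyte-like cells in the 3 hematoma libraries that held at least 20 of each. FOXP2 (chromosome 7, 114086327 to 114693772), a transcription factor gene, had 317 counts in microglia-like cells, 113 ± 59.2 CPM (n = 3), and 0 in monocyte-like cells, at least 517-fold higher against 3 counts over the group. FAM149A had 251 counts against 1, a ratio of 1229 with a counting interval of 218 to 48720, and MCF2L 270 against 2, a ratio of 661 with an interval of 181 to 5484. The synapse gene SYNDIG1 was higher by 9.04 ± 0.56 on the log2 scale. JAKMIP2 had 0 counts in microglia-like and 1336 in monocyte-like cells, at least 91.0-fold lower, and TFPI 2 against 1189, a ratio of 121.5 with an interval of 33.5 to 1004. The clusters were made from expression, so the count of genes describes how far they stood apart, and genes that led them are not given as results. With the library as a block, 796 of 8330 genes differed, 437 higher and 359 lower in microglia-like cells (edgeR, n = 3), and 481 without the block. Without replicate 8 the count was 461. Each library held 20 to 77 microglia-like cells.

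Depth and quality per cell were compared between the groups. Library medians averaged 8046 ± 530 UMIs per cell in blood and 8232 ± 3222 in hematoma (n = 6 each, exact permutation p = 0.929). Genes per cell averaged 2801 ± 184 and 2716 ± 712 (exact permutation p = 0.803), and mitochondrial UMIs 5.13% ± 0.863 and 3.91% ± 1.30 (exact permutation p = 0.0887). The median cell held no hemoglobin UMI in any hematoma library (mean 0.00644% ± 0.0158 in blood, exact permutation p = 1). None of these 4 measures passed the adjusted threshold (0 of 4, lowest adjusted p = 0.355). Mitochondrial UMIs were lower in hematoma in 5 of 6 patients. Within classes no measure passed either. In NK cell-like cells UMIs per cell (5715 and 4707, exact permutation p = 0.208) and genes per cell (2499 and 2229, exact permutation p = 0.290) were lower in hematoma in 5 of 5 patients. In B cell-like cells mitochondrial UMIs (6.40% and 5.01%, exact permutation p = 0.176) were lower in 4 of 4.

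In the 4 patients outside the comparisons, the labelled difference in gene levels ran opposite to that of the other 6. Over the genes called in each of the 4 cell classes, the labelled hematoma minus blood difference correlated negatively with the log2 fold changes above in 4 of 4 patients, a correlation over genes, which are not replicates. With cells of shared barcodes left out, the shares of microglia-like, neural or glial-like and platelet-like cells ran opposite in 4 of 4 of these patients, and that of monocyte-like cells in 2. In those libraries 1295 microglia-like cells stood under the label blood, among 16758 cells, and 0 under the label hematoma, among 33495 cells. For these 4 patients the gene levels and the microglia-like cells argue against the labels and go with the file names. With all 10 patients and these 4 file pairs exchanged, 4455 genes were called in monocyte-like, 832 in T cell-like, 1430 in NK cell-like and 942 in B cell-like cells (edgeR).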

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

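Among the tests below, those over the fallen list members alone, of the second free-RNA fraction, of handling stress and of barcodes shared between libraries were chosen after the result was seen. A single library stood apart from the others of its group in 20 of 238 groups of 4 to 6 libraries, where chance gives about 11.9. The shares were 14.7% B cell-like and 7.75% unnamed cells in hematoma, and 6.70% platelet-like and 0.414% progenitor-like cells in blood. One blood library had a median of 0.0386% hemoglobin UMIs. In monocyte-like cells of 1 blood library the levels standing apart were 0.303 CPM of FABP4, 4.84 of MARCO, 14.1 of EREG, 9.22 of FABP5 and 69.5 of PLIN2. In monocyte-like cells of 1 hematoma library each they were 0.726 CPM of DUSP4, 174 of LDHA, 0 of PTGES and 187 of CFP. In T cell-like cells of hematoma they were 139 CPM of PMEPA1, 92.4 of BCL2 and 0.209 of PF4. In NK cell-like cells they were 138 CPM of CX3CR1 and 0.195 of PF4 in hematoma and 19.4 of P4HA1 in blood.

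The effect of hematoma differed between monocyte-like and T cell-like cells in 2339 genes by the test of the interaction. The log2 differences, monocyte-like minus T cell-like, were 11.46 for CXCL5, 10.41 for PPBP, 10.14 for SLC16A10, 9.90 for CCL20, 9.44 for ANGPTL4, 9.20 for TFPI, -3.97 for DACH1, -3.77 for CLEC4A, -3.71 for RGS2, -3.52 for HSPA6 and -3.29 for JAML. In the libraries outside the comparisons, the difference in gene levels as labelled went the opposite way in 4 of 4 patients in each of the 4 classes, the share of monocyte-like cells went the opposite way in 2 of 4, and 1295 microglia-like cells stood in libraries labelled blood.

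Genes of monocytes and platelets were lower in lymphocyte-like cells of hematoma, and free RNA in the cell suspension may be the source of their counts in blood. A test used 9 alarmin and platelet genes, taken because they fell in T, NK and B cell-like cells. Their log2 ratio between 2 classes of blood varied by an SD of at most 0.287 beyond counting error. A shared pool of free RNA would give a small spread, but 1 ratio for all 9 held only roughly. The platelet genes PPBP, PF4 and CAVIN2 stood at 16.1, 10.9 and 5.45 CPM in T and 33.0, 18.9 and 8.61 CPM in B cell-like cells. The monocyte genes lay closer, the widest apart being S100A12 at 5.66 and 7.83 CPM. In blood, 94 genes stood at 50 CPM or more in monocyte-like cells, 20 or more times the level in each lymphocyte class. Over this wider set the ratio varied by up to 1.04 (SE 0.0793). This passed the limit of 1 set in advance as speaking against free RNA. It lies within its error of that limit, a condition added after the value was seen, so the wider set leaves free RNA open. Of these genes, 24 of 69 tested fell in T, 15 of 33 in NK and 11 of 40 in B cell-like cells, and 0, 2 and 3 rose. Doublets were argued against, since the 1% of blood lymphocyte-like cells with the most S100A8, S100A9 and LYZ UMIs held 8.77% of them, where under 20% was set in advance as excluding them. A change in the lymphocytes themselves was not tested and stays open.

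The lists of hypoxia response and glycolysis genes were called higher in all 4 classes of hematoma, though not every member passed (in T cell-like cells 11 of 22 and 8 of 19 rose). No call held with an estimated correlation (adjusted p = 0.207, 0.234, 0.160 and 0.209 for monocyte-like, T, NK and B cell-like cells, alike for both lists). With thinned cells at least 90.04% of the median log2 fold change of these lists was kept in each class. Thinning draws on the UMIs of all genes alike and keeps their proportions on average. The value thus cannot decide whether depth per cell plays a part, which stays open. With a fraction from the upper 10% of macrophage genes, free RNA of macrophages gave a median of 57.4% of the rise in lymphocyte-like cells. It gave 13.7% with one from the fixed macrophage list. Both fractions are upper limits. SPP1 stood in these cells at 0.791% to 0.990% of its level over all cells, APOE at 0.487% to 2.26%, and the lowest gene gives 0. The prediction that 57.4% would speak for free RNA was thus wrong. At the tighter limit free RNA gave over 50% of the rise for 1 of 51 members that rose, counted per class. Free RNA was taken to stand in the proportions of the captured cells. Under that condition the value argues against free RNA of macrophages as the source of most of the rise. Free RNA in other proportions, such as that of cells lost before loading, was not bounded. A smaller part cannot be told apart. Stress between sampling and loading cannot be told apart either, since the list of immediate early and heat shock genes was called higher in 4 of 4 classes, with 12, 4, 7 and 6 of 23 members up and no call with an estimated correlation (adjusted p = 0.335, 0.675, 0.758 and 0.484), and the design has no sample handled another way. Low oxygen or a glycolytic state in the hematoma is a biological explanation that may hold and was not tested.

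The 273 neural or glial-like cells in blood may be molecules of another library read under the same cell barcode. Of them 100% had a barcode that stood in another library at 5 or more times the UMIs, against 9.70% of 2403 other blood cells of the same depth. No biological explanation was tested. With such barcodes left out, 2 classes differed in share rather than 1.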

How the results depend on the processing

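Leaving out cells with barcodes shared between libraries and sums of under 100 cells were alternatives chosen after the data were seen. With all 10 patients as labelled, 0 genes were called by edgeR in monocyte-like, T, NK and B cell-like cells and in the interaction, and 0 classes in share, since 4 patients then ran the other way; with their files exchanged the counts were 942 in B cell-like cells, 3823 in the microglia comparison, 3856 in the interaction and 4 classes in share. As labelled, the log2 fold changes turned for EREG (-0.51), CAVIN2 (0.58), CRYAB (-1.74) and IER3 (-0.54) in monocyte-like, S100A8 (0.15), S100A9 (0.13), LYZ (0.11) and PF4 (0.89) in T, PMEPA1 (-0.50), S100A8 (0.43), LYZ (0.25), PF4 (0.87) and PPBP (0.86) in NK and S100A8 (0.06), LYZ (0.28), ATF3 (-0.35) and CCR7 (-0.07) in B cell-like cells, and for TFPI (-0.04) in the interaction. The shares of microglia-like (-1.83 percentage points) and platelet-like cells (0.973) turned as well, as did the platelet list, higher in NK (adjusted p = 0.0074) and B cell-like cells (adjusted p = 0.000326). The share of NK cell-like cells turned with files exchanged (-0.568 points), and that of neutrophil-like cells ranged from -1.37 to 1.81 points with 1 patient left out, the cause of which was not tested.

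Thinning to 1000 UMIs, which also left out cells with fewer, gave fewer genes. The counts were 1483, 289, 508 and 210 in monocyte-like, T, NK and B cell-like cells. The patient as a block, with complete pairs alone, gave 1889 genes in T and 2066 in NK cell-like cells, against 438 and 994 in the same libraries without it, and gave 3226 in monocyte-like and 607 in B cell-like cells. It gave 0 classes in share, where the smallest sign-flip p of 6 pairs (0.0312) leaves little room over 15 classes, so this says nothing about stability. DESeq2 gave 1203 genes in T and 1050 in B cell-like cells. The microglia comparison gave 481 genes without its block and 1565 with no low-count filter. The stricter cell filter gave 0 classes in share and shared barcodes left out 2. Camera called 0 of 90 list tests with an estimated correlation, against 42. The cause was not tested, except that thinned sums hold fewer UMIs, fewer cells and fewer genes tested by construction. With 1 patient left out the counts ranged from 154 to 454 in T, 454 to 1132 in NK, 168 to 421 in B cell-like cells, 461 to 819 in the microglia comparison and 0 to 3 classes in share.

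With no low-count filter the median log2 fold change shifted by -0.166 in monocyte-like cells, -0.210 in the microglia comparison and -0.109 in the interaction, and with at least 100 cells per sum by -0.196 in the interaction. The 117 genes named had been chosen because they kept direction and call where tested, except as labelled, where 93 lost the call and 18 turned. With thinned cells 84 of them were tested, with the stricter filter 99, with the patient as a block 99 and with doublets kept or Leiden resolution 0.5 100. The block called 7 further list tests and ended none. Hematoma libraries held 612 to 6335 cells each and blood libraries 5554 to 8058.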

Other observations

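The genes in the next paragraph and the counts of other splits were chosen or tested after the results were seen.

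In all 4 classes of hematoma, 30 genes rose and 18 fell, where independent lists would share 0.0340 and 0.0146, though the classes come from the same libraries. HIF1A, the oxygen-regulated transcription factor, had log2 fold changes of 1.36, 0.86, 1.47 and 1.20 in monocyte-like, T, NK and B cell-like cells, and EGLN1, which targets it for breakdown, of 1.02, 0.96, 1.18 and 0.98. The co-chaperone BAG3 had 3.66, 1.09, 2.85 and 3.13. Among the genes that fell, the integrin ITGB2 had -0.68, -1.32, -1.05 and -1.40. Of the 18, S100A8, S100A9, S100A12, LYZ and FCN1 are monocyte genes and CAVIN2 a platelet gene. In blood, S100A12 stood at 5.66 CPM in T cell-like and 1932 CPM in monocyte-like cells. Cluster 32, led by C1QC, SPP1, APOE and TREM2, stood between the microglia and monocyte markers and stayed unnamed, with 26 cells in blood and 154 in hematoma.

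Other splits of the same libraries were counted. In monocyte-like cells 1 of 100 splits, the real one, gave as many as 3245 genes, and the highest other gave 682. In T cell-like cells it was 1 of 100 (648, highest other 312), in NK cell-like cells 1 of 100 (1080, 38), and in the interaction 1 of 50 (2339, 5). These shares are under 0.05, but the splits ignore the pairs. Among the splits that part each pair of libraries of a patient, 1 of 32, the real one, gave as many genes in monocyte-like cells (highest other 162). The same held in T (0) and NK cell-like cells (506) and in the interaction (495). That share of 3.125% is the smallest that 32 splits allow and leaves little room over several results. Chance is thus argued against for each of these results taken alone. In B cell-like cells 1 of 100 splits gave as many (613, highest other 1), but these ignore the pairs, and the 16 splits that part each pair (1 as large, highest other 0) are too few for a share under 0.05. The microglia comparison had 1 of 4 splits (796, highest other 0), too few for a share under 0.05. For the 42 lists called, 6 of 100 splits gave as many (highest other 49), so chance cannot be excluded.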
